A study of Caenorhabditis elegans with 24 samples.

How the data were processed

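The values come from 6 deposited gene-level tables, 1 for each comparison the authors made. Per the labels, reads were quantified with kallisto and compared with sleuth on the WBcel235 genome build. The versions of both tools, the sleuth test and the transcript filter are not given in the sources used here. Each deposited table gives a gene identifier, a symbol, a p-value, a q-value, the effect on the natural log scale, the mean abundance of each of both groups, and their ratio as a fold and on the log2 scale. The headers name no unit for the means. They were read as the authors' mean TPM, the kallisto abundance unit scaled to a fixed total per library. The genes of a table sum to about 0.7 of that total. Each mean is the authors' sum or value over the transcripts kept for that gene, so the totals differ between tables.

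The authors' natural log effect was divided by the natural log of 2 to give a log2 change. Its sign was turned in the tables of both NaCl comparisons, so that a positive value stands for more RNA in the stressed, mutant or knockdown group. The authors' q-value equals the Benjamini-Hochberg adjustment of the authors' p-value, and a gene was called raised or lowered at q below 0.05. The standard error behind the authors' p-value was derived as the absolute log2 change divided by the normal quantile of the 2-sided p-value. It is called the implied standard error, follows each log2 change after "±", and has no value where the listed p-value is 0. These p-values measure the spread between biological replicates. Values of single libraries were not used here. So no count depth, per-replicate value, replicate block, other sample split, leave-one-out fit or number of samples showing a direction could be had.

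Before the data were examined, 33 gene lists were fixed, of which 32 were tested; the other holds the targeted genes skn-1 and dpy-7. The tested lists are osmolyte synthesis and transport, trehalases, aquaporins, osmotic response regulators, SKN-1 detoxification targets, glutathione S-transferases, UDP-glucuronosyltransferases, cytochrome P450s, epidermal antimicrobial peptides, annular furrow collagens, other named cuticle collagens, numbered collagens, molting and hedgehog-related genes, heat shock proteins, the endoplasmic reticulum (ER) unfolded protein response, mitochondrial chaperones, DAF-16 targets, pathogen response genes, vitellogenins, lysosomal proteases, fatty acid metabolism, glucose and glycogen metabolism, proteasome subunits, cytosolic ribosomal proteins, histones, and markers of oocyte and eggshell, early zygotic embryo, sperm, muscle, intestine, neurons and epidermis. Lists with at least 3 measured members were tested with cameraPR of limma on the signed normal score of each p-value, limited to 38 in size, with a preset correlation between genes of 0.01. The p-values were adjusted by Benjamini-Hochberg over the lists of 1 comparison. A correlation of 0.05 was the alternative, together with a rank version and with 10000 random lists of the same size and abundance. A correlation estimated from the data was impossible without library values. Counts "adjusted over the list alone" use the Benjamini-Hochberg adjustment over the members of 1 list.

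A naming rule also fixed before the data were examined takes skn-1, dpy-7, gpdh-1, hmit-1.1, gst-4, gcs-1, nlp-29 and cnc-2 in each comparison. It adds the 5 raised and the 5 lowered genes with the largest absolute change among those past the threshold that have a symbol and a mean abundance above the lowest 25 percent. Up to 4 members of each fixed list that passed the threshold with the smallest p-values complete it. Other genes named in the text were chosen after their values were seen.

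Differences between comparisons were tested with the normal score of the difference of the log2 changes over the root of the summed squared implied standard errors. They were computed for 8 genes in 4 pairs of comparisons, 32 tests adjusted together by Benjamini-Hochberg, and for the lists with cameraPR. Overlaps of called genes were set against the number that independent calls would give, with Fisher's exact test (1-sided) over the genes that have a p-value in both tables. Genes are not independent replicates, so these p-values describe the overlap and not its certainty. Groups shared between comparisons create covariance of the errors, which was simulated 100 times from the implied standard errors. For the genes raised in a stress comparison, the share lowered by skn-1 RNAi was also set against 1000 draws of genes not raised, matched for mean abundance in 20 bins.

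The procedure was tested on simulated data, where 100 genes of each comparison changed by 1 log2 unit and another 100 by 3. Errors were drawn from the implied standard errors, so this tests the steps used here and not the authors' calls. A change of 1 was called in 61 to 77 genes and of 3 in 94 to 98. False calls among all other genes numbered 5 to 17. A shifted list was recovered by cameraPR.

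The alternatives fixed before the data were examined and run were q thresholds of 0.01 and 0.1, a Benjamini-Hochberg adjustment computed again, a minimum absolute log2 change of 1, and leaving out the lowest 25 percent of genes by abundance. One alternative chosen after seeing the data was a shift called equal total TPM. It subtracts the log2 ratio of the total TPM of both groups from each fitted log2 change. Others chosen then left out genes whose listed level in the same libraries departs by over 10 percent between tables. The last left out genes whose effect and ratio of means differ in sign. Equal total TPM adds 0.11 to each log2 change in 24 h NaCl and 0.17 in the dpy-7 mutant, and at most 0.02 elsewhere. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1. Gene coordinates are from the WBcel235 annotation of Ensembl.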

Results

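RNA abundance was measured by Illumina sequencing of total RNA from whole Caenorhabditis elegans, collected as gravid young adults. The 24 libraries fall into 8 groups of 3 biological replicates. Worms of the wild-type strain N2 were kept at 51 mM NaCl, the usual salt of the agar, or moved to 300 mM NaCl for 3 h or 24 h. Both stress durations were also studied with RNA interference (RNAi) against skn-1, the gene of a transcription factor of oxidative and xenobiotic stress defence. The strain CB88 carries dpy-7(e88), a mutation in a collagen of the annular furrows of the cuticle, and was studied with control RNAi and with skn-1 RNAi. The labels give no salt level and no time for the dpy-7 groups. No group joins skn-1 RNAi with N2 at 51 mM NaCl, so the effect of the RNAi without stress was not analysed here. Replicates of the skn-1 RNAi groups at 24 h and in dpy-7 are numbered 2 to 4 in the labels.

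The tables hold 14605 to 15032 genes per comparison. Of these, 4 to 20 per table have no p-value. The depth of the libraries is unknown. The median implied standard error of a log2 change was 0.15 to 0.19. On WBcel235 skn-1 (WBGene00004804) lies on chromosome IV at 5651039-5660384, and dpy-7 (WBGene00001069) on X at 7536467-7537792. There gpdh-1 (WBGene00009824) lies on I at 14075837-14078211 and hmit-1.1 (WBGene00013073) on V at 18516789-18523875. Genes gst-4 (WBGene00001752) and gcs-1 (WBGene00001527) lie on IV at 10142225-10143099 and on II at 9035562-9038301. Both nlp-29 (WBGene00003767) and cnc-2 (WBGene00000556) lie on V at 3984425-3984847 and 1449665-1450183.

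The comparison of 300 with 51 mM NaCl at 3 h asks which genes respond early to osmotic stress. Means of the authors' deposited table show a rise of gpdh-1, which makes the osmolyte glycerol, from 7.61 to 147 TPM (log2 change 4.27 ± 0.17, q = 8.8e-134). The epidermal antimicrobial peptide gene nlp-29 (24.5 to 287 TPM, 3.54 ± 0.14) and the glutathione S-transferase gene gst-4 (32.8 to 143 TPM, 2.12 ± 0.09) rose with it in the authors' deposited table. The inositol transporter hmit-1.1 (4.27 to 3.40 TPM, -0.33 ± 0.16, q = 0.1) and the peptide gene cnc-2 (6.03 to 9.52 TPM, 0.62 ± 0.44, q = 0.29) did not pass the test of the authors' deposited table. In the authors' deposited table the glutathione synthesis gene gcs-1 (61.6 to 77.2 TPM, 0.32 ± 0.06) and the mutated collagen gene dpy-7 (10.6 to 20.0 TPM, 0.94 ± 0.22) rose, while skn-1 (23.3 to 22.2 TPM, -0.07 ± 0.05, q = 0.31) did not pass. Over all genes 2528 rose and 2663 fell of 15013, of which 903 and 601 changed more than 2-fold. At q below 0.01 1906 rose and 1826 fell.

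The 5 largest rises at 3 h in the authors' deposited table, among genes with a symbol and above the lowest 25 percent of abundance as in each comparison, were sri-39, listed at 0 in the control and at 33.6 TPM under stress, numr-1 (1.05 to 134 TPM), irg-2 (6.66 ± 0.37), and the histone copies his-9 and his-13, whose values are identical and cannot be assigned to either. The 5 largest falls of the authors' deposited table were pes-10 (12.1 to 0.134 TPM, -6.26 ± 0.57), ets-7 (-5.96 ± 0.58), fbxb-17 (-5.79 ± 0.98), sdz-16 (-5.69 ± 0.78) and ccch-2 (-4.93 ± 0.72). Here pes-10 is a gene of the first zygotic transcription in the embryo.

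Of the osmolyte genes, 9 of 11 measured members rose, 0 fell and 2 did not pass the test (adjusted over the list alone, 10 rose and 1 fell), with median log2 change 1.28 and adjusted p = 2.4e-31. Glycerol phosphatase genes C53A3.2 (3.83 ± 0.20) and F44E7.2 (2.73) and the glycerol 3-phosphate dehydrogenase gene gpdh-2 (1.88 ± 0.05) rose in the authors' deposited table. The epidermal antimicrobial peptides had 10 raised and 1 lowered of 17 (adjusted over the list alone 10 and 2, median 1.06, adjusted p = 2.3e-05), among them cnc-4 (2.82 ± 0.16), nlp-31 (2.77 ± 0.25) and nlp-28 (1.65 ± 0.18) in the authors' deposited table. Targets of the transcription factor DAF-16 had 7 raised and 0 lowered of 11 (adjusted over the list alone 7 and 0, median 1.01, adjusted p = 7.2e-05). The authors' deposited table shows the small heat shock gene hsp-12.6 (4.94 ± 0.37), the glyoxylate cycle gene icl-1 (2.26 ± 0.12) and the catalase gene ctl-1 (1.01 ± 0.15) as raised. The SKN-1 detoxification targets had 5 raised and 0 lowered of 16 (adjusted over the list alone 5 and 0, median 0.22, adjusted p = 0.0056). Beside gst-4 and gcs-1, gst-5 (1.65 ± 0.12) and the arsenite response gene aip-1 (0.62 ± 0.07) rose in the authors' deposited table. Cytochrome P450 genes had 24 raised and 6 lowered of 60 (adjusted over the list alone 26 and 7, median 0.66, adjusted p = 1.7e-04). Pathogen response genes had 3 raised and 5 lowered of 15 (adjusted over the list alone 3 and 5, median -0.23, adjusted p = 0.0081, or adjusted p = 0.057 with a correlation of 0.05), and the authors' deposited table shows the lysozyme genes lys-2 (-2.41) and lys-1 (-1.01 ± 0.05) lowered and lys-8 (0.59 ± 0.07) raised.

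Early zygotic markers had 2 raised and 13 lowered of 17 (adjusted over the list alone 2 and 13, median -2.05, adjusted p = 6.1e-07). Sperm genes had 29 raised and 0 lowered of 60 (adjusted over the list alone 36 and 0, median 0.41, adjusted p = 0.0019, or adjusted p = 0.094 with a correlation of 0.05). Histones had 20 raised and 2 lowered of 54 (adjusted over the list alone 20 and 2, median 0.53, adjusted p = 0.0056, or adjusted p = 0.14 with a correlation of 0.05). Intestine markers had 3 raised and 5 lowered of 11 (adjusted over the list alone 3 and 5, median 0.03, adjusted p = 0.16). Lowered and raised intestine genes in the authors' deposited table were the peptide transporter pept-1 (-1.79 ± 0.08), the intermediate filament ifc-2 (-1.64 ± 0.08) and the transporter pgp-1 (2.38 ± 0.10). Furrow collagens had 4 raised and 0 lowered of 6 (adjusted over the list alone 4 and 0, median 0.78, adjusted p = 0.17). The authors' deposited table gives dpy-3 (1.01 ± 0.20), dpy-2 (0.88 ± 0.26) and dpy-10 (0.69 ± 0.11) as raised. Genes of fatty acid metabolism had 4 raised and 10 lowered of 22 (adjusted over the list alone 4 and 10, median -0.21, adjusted p = 0.098), and the authors' deposited table shows the elongases elo-6 (-2.63 ± 0.09), elo-5 (-1.56 ± 0.07) and elo-2 (-1.23 ± 0.06) lowered.

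The set test did not pass for trehalases (1 and 2 of 5), aquaporins (3 and 1 of 12), osmotic response regulators (3 and 1 of 12), glutathione S-transferases (5 and 4 of 34), UDP-glucuronosyltransferases (16 and 13 of 58), other named cuticle collagens (3 and 0 of 13) and numbered collagens (20 and 20 of 115), with raised and lowered members in brackets here and below. Nor did it pass for molting and hedgehog-related genes (8 and 4 of 23), heat shock proteins (4 and 2 of 18), ER unfolded protein response genes (3 and 4 of 13), mitochondrial chaperones (1 and 0 of 4), vitellogenins (0 and 2 of 6), lysosomal proteases (2 and 1 of 11) and glucose and glycogen metabolism (2 and 3 of 20). It also missed the threshold for proteasome subunits (0 and 5 of 32), cytosolic ribosomal proteins (1 and 1 of 78), oocyte and eggshell markers (0 and 8 of 24), muscle markers (5 and 0 of 16), neuron markers (4 and 1 of 17) and epidermis markers (4 and 2 of 15). Adjusted p of these lists lay from 0.098 to 0.79. Adjusted over the list alone, these counts were glutathione S-transferases (5 and 3), numbered collagens (22 and 21), molting and hedgehog-related genes (9 and 4), proteasome subunits (0 and 4), cytosolic ribosomal proteins (0 and 0), oocyte and eggshell markers (0 and 9), neuron markers (4 and 0) and otherwise unaltered. Median and test had opposite signs for trehalases (-0.16, test up), numbered collagens (0.17, test down) and intestine markers (0.03, test down). Against random lists of equal size and abundance, the call was lost for SKN-1 detoxification targets (0.08), with the adjusted p in brackets.

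At 24 h the same salt contrast asks which changes persist. In the authors' deposited table the osmolyte genes gpdh-1 rose from 1.03 to 57.0 TPM (5.74 ± 0.34) and hmit-1.1 from 1.58 to 53.8 TPM (5.03 ± 0.18). The peptide genes nlp-29 (38.5 to 603 TPM, 3.93 ± 0.15) and cnc-2 (7.40 to 21.2 TPM, 1.53 ± 0.47, q = 0.0038) rose in the authors' deposited table, as did gst-4 (83.6 to 115 TPM, 0.45 ± 0.19, q = 0.043). Values of gcs-1 (93.3 to 82.6 TPM, -0.20 ± 0.11, q = 0.11), skn-1 (-0.12 ± 0.08, q = 0.18) and dpy-7 (0.40 ± 0.34, q = 0.34) in the authors' deposited table did not pass the test. Over all genes 3250 rose and 3431 fell of 14770, with 1565 and 631 changed more than 2-fold. With equal total TPM in both groups 3989 rose and 2272 fell, and without the lowest 25 percent of abundance 2376 rose and 3321 fell.

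At 24 h the largest rises of the authors' deposited table were the antimicrobial peptide gene cnc-6 (0.155 to 371 TPM, 10.39 ± 0.66), clx-1 (9.52 ± 0.65), fbxa-155 (listed at 0 in the control and at 17.9 TPM under stress), numr-1 (8.11 ± 0.42) and nspe-7 (7.24 ± 0.61). The largest falls of the authors' deposited table were all in the family of pud genes, pud-3 (-4.96 ± 1.46), pud-1.1 (-4.30 ± 1.08), pud-4, and pud-2.1 and pud-2.2, which share the value -4.11 ± 1.02 and cannot be told from each other.

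Osmolyte genes had 9 raised and 0 lowered of 11 (adjusted over the list alone 9 and 0, median 1.22, adjusted p = 5.2e-14). The authors' deposited table shows hmit-1.2 (2.36 ± 0.17) and F44E7.2 (1.22 ± 0.09) as raised. Antimicrobial peptides had 11 raised and 3 lowered of 18 (adjusted over the list alone 12 and 3, median 1.26, adjusted p = 1.5e-07). Cytochrome P450 genes had 37 raised and 10 lowered of 63 (adjusted over the list alone 37 and 11, median 0.91, adjusted p = 1.0e-06). UDP-glucuronosyltransferases had 26 raised and 9 lowered of 59 (adjusted over the list alone 26 and 9, median 0.41, adjusted p = 0.0046, or adjusted p = 0.13 with a correlation of 0.05). Of both families the authors' deposited table shows cyp-14A5 (3.23 ± 0.10), cyp-13A5 (2.92 ± 0.12), ugt-29 (3.62 ± 0.12) and ugt-26 (3.00 ± 0.16) as raised. DAF-16 targets had 8 raised and 1 lowered of 12 (adjusted over the list alone 8 and 1, median 0.80, adjusted p = 3.6e-04). The authors' deposited table has the metallothionein gene mtl-1 (3.12 ± 0.16) and the ferritin gene ftn-1 (4.72 ± 0.32) as raised. Vitellogenins, the yolk proteins made in the intestine, had 0 raised and 3 lowered of 6, 3 without a p-value (adjusted over the list alone 0 and 3, median -1.79, adjusted p = 3.6e-04). Their means in the authors' deposited table fell for vit-3 (2713 to 684 TPM, -2.07 ± 0.27) and vit-4 (-1.79 ± 0.22). The authors' deposited table has no p-value for vit-2 (1189.7 to 758 TPM), vit-5 (4168 to 1725 TPM) and vit-6 (2402 to 1358 TPM), which the median leaves out. The level of vit-6 in the same control libraries departs by -33.4% in the dpy-7 table. Proteasome subunits had 0 raised and 18 lowered of 32 (adjusted over the list alone 0 and 18, median -0.29, adjusted p = 3.6e-04). Ribosomal proteins had 20 raised and 1 lowered of 78 (adjusted over the list alone 10 and 0, median 0.15, adjusted p = 0.045, or adjusted p = 0.31 with a correlation of 0.05).

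Oocyte markers had 0 raised and 14 lowered of 24 (adjusted over the list alone 0 and 20, median -0.33, adjusted p = 4.7e-04). Early zygotic markers had 0 raised and 13 lowered of 18 (adjusted over the list alone 0 and 13, median -1.12, adjusted p = 0.0016). Sperm genes had 17 raised and 0 lowered of 47 (adjusted over the list alone 16 and 0, median 2.20, adjusted p = 0.0067, or adjusted p = 0.13 with a correlation of 0.05). Examples in the authors' deposited table are mex-6 (-0.66 ± 0.08), pes-10 (-1.68 ± 0.26), vet-2 (-1.03 ± 0.11) and the sperm gene ssp-35 (4.68 ± 0.79). Epidermis markers had 4 raised and 3 lowered of 15 (adjusted over the list alone 4 and 3, median -0.03, adjusted p = 0.84). SKN-1 detoxification targets had 3 raised and 6 lowered of 17 (adjusted over the list alone 5 and 6, median -0.20, adjusted p = 0.53). The authors' deposited table lists gst-5 (1.12 ± 0.10) as raised and gst-13 (-1.17 ± 0.14) and gst-7 (-0.84 ± 0.10) as lowered. Other cuticle collagens had 3 raised and 8 lowered of 13 (adjusted over the list alone 3 and 8, median -1.23, adjusted p = 0.27). The authors' deposited table has dpy-17 (1.81 ± 0.09) and dpy-14 (1.78 ± 0.09) as raised and dpy-4 (-1.98 ± 0.55) as lowered.

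The set test did not pass for trehalases (2 and 1 of 5), aquaporins (3 and 4 of 11), osmotic response regulators (4 and 0 of 12), glutathione S-transferases (9 and 11 of 36), annular furrow collagens (0 and 0 of 6) and numbered collagens (33 and 28 of 118). Nor did it pass for molting and hedgehog-related genes (11 and 2 of 23), heat shock proteins (4 and 2 of 18), ER unfolded protein response genes (2 and 2 of 13), mitochondrial chaperones (1 and 0 of 4), pathogen response genes (7 and 6 of 16) and lysosomal proteases (3 and 4 of 11). It also missed the threshold for fatty acid metabolism (6 and 4 of 20), glucose and glycogen metabolism (5 and 5 of 20), histones (10 and 6 of 49), muscle markers (6 and 3 of 16), intestine markers (5 and 3 of 11) and neuron markers (4 and 0 of 17). Adjusted p of these lists lay from 0.082 to 0.94. Adjusted over the list alone, these counts were glutathione S-transferases (10 and 11), numbered collagens (33 and 31), molting and hedgehog-related genes (12 and 2), pathogen response genes (8 and 6), histones (10 and 5), intestine markers (5 and 4), neuron markers (3 and 0) and otherwise unaltered. Median and test had opposite signs for trehalases (-0.05, test up), glutathione S-transferases (just below 0, test up), other named cuticle collagens (-1.23, test up), numbered collagens (0.16, test down), lysosomal proteases (-0.06, test up), glucose and glycogen metabolism (-0.08, test up) and histones (-0.29, test up). Against random lists the call was lost for UDP-glucuronosyltransferases (0.17), proteasome subunits (0.27) and oocyte and eggshell markers (0.16). Equal total TPM adds 0.11 to each log2 change here. That turns the medians of trehalases, aquaporins, glutathione S-transferases, ER genes, lysosomal proteases, glucose and glycogen metabolism and epidermis markers from negative to positive. It leaves proteasome subunits at -0.18, oocyte markers at -0.22 and ribosomal proteins at 0.26.

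The dpy-7 comparison asks what a mutation of a furrow collagen does. Its control is the 24 h N2 group at 51 mM NaCl that also serves the 24 h salt comparison. In the authors' deposited table the osmolyte genes gpdh-1 (1.05 to 71.9 TPM, 6.05 ± 0.30) and hmit-1.1 (1.62 to 51.8 TPM, 4.93 ± 0.17) rose in the mutant. Antimicrobial peptide genes nlp-29 (39.3 to 508 TPM, 3.64 ± 0.14) and cnc-2 (7.54 to 71.6 TPM, 3.21 ± 0.42) and the detoxification gene gst-4 (85.4 to 229 TPM, 1.39 ± 0.20) rose as well in the authors' deposited table, while gcs-1 (95.4 to 57.6 TPM, -0.77 ± 0.11) fell. RNA of the mutated gene dpy-7 (21.8 to 44.4 TPM, 1.04 ± 0.33, q = 0.0034) was raised in the authors' deposited table. There skn-1 (26.9 to 24.1 TPM, -0.21 ± 0.08, q = 0.011) was lowered, a call that ended with equal total TPM (-0.04, adjusted p = 0.67). Over all genes 4168 rose and 4533 fell of 14865, with 2370 and 397 changed more than 2-fold. At equal total TPM 5024 rose and 2534 fell, and without the lowest 25 percent of abundance 3008 rose and 4468 fell.

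The mutant's largest rises in the authors' deposited table were catp-2 (9.24 ± 0.73), the lysozyme gene ilys-2 (9.19 ± 0.65), cnc-6 (8.23 ± 0.68), the lipase gene lips-11 (7.96 ± 1.12) and ilys-3, listed at 0 in the control and at 37.3 TPM in the mutant. Its largest falls in the authors' deposited table were pud-3 (-7.94 ± 1.04) (whose control level differs by over 10 percent between tables), pud-4 (-6.82 ± 0.80), the lectin gene clec-47 (-5.83 ± 0.91), the collagen gene col-107 (-5.80 ± 0.30) and irg-3 (396 to 7.79 TPM, -5.71 ± 0.19).

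Of the antimicrobial peptides, 16 of 18 measured members rose, 0 fell and 2 did not pass the test (adjusted over the list alone, 16 rose and 0 fell), with median log2 change 2.64 and adjusted p = 1.6e-13. Among them nlp-34 (9.77 to 828 TPM, 6.36 ± 0.35), nlp-31 (3.05 ± 0.16) and cnc-4 (2.79 ± 0.20) rose in the authors' deposited table. Osmolyte genes had 10 raised and 0 lowered of 11 (adjusted over the list alone 10 and 0, median 1.62, adjusted p = 1.2e-12). The authors' deposited table gives C53A3.2 (3.97 ± 0.25) and F44E7.2 (1.71 ± 0.08) as raised. Osmotic response regulators, a list of genes whose loss alters salt tolerance or osmolyte genes, had 10 raised and 0 lowered of 12 (adjusted over the list alone 10 and 0, median 0.73, adjusted p = 1.2e-04). Molting and hedgehog-related genes had 17 raised and 2 lowered of 23 (adjusted over the list alone 17 and 2, median 1.18, adjusted p = 9.3e-06). The authors' deposited table lists grl-21 (4.87 ± 0.39), noah-2 (1.74 ± 0.14) and wrt-2 (1.68 ± 0.14) as raised. Among the collagens, the furrow list had 4 raised and 2 lowered of 6 (adjusted over the list alone 4 and 2, median 1.02, adjusted p = 0.46). The other named list had 4 raised and 8 lowered of 13 (adjusted over the list alone 4 and 8, median -1.63, adjusted p = 0.88). The numbered list had 57 raised and 27 lowered of 116 (adjusted over the list alone 58 and 27, median 0.75, adjusted p = 0.18). Values in the authors' deposited table went both ways, with dpy-2 (1.31 ± 0.27), dpy-10 (1.17 ± 0.17), dpy-14 (3.10 ± 0.10), dpy-17 (3.07 ± 0.16), col-165 (3.59 ± 0.19) and col-65 (2.95 ± 0.11) raised and dpy-5 (-2.09 ± 0.19) and col-101 (-2.69 ± 0.08) lowered.

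Markers of epidermis, the tissue that secretes the cuticle, had 9 raised and 2 lowered of 15 (adjusted over the list alone 9 and 2, median 1.01, adjusted p = 0.01). Muscle markers had 11 raised and 1 lowered of 16 (adjusted over the list alone 11 and 1, median 0.60, adjusted p = 6.0e-04). Neuron markers had 11 raised and 0 lowered of 17 (adjusted over the list alone 11 and 0, median 0.67, adjusted p = 0.028, or adjusted p = 0.1 with a correlation of 0.05). Intestine markers had 6 raised and 3 lowered of 11 (adjusted over the list alone 6 and 3, median 0.30, adjusted p = 0.049, or adjusted p = 0.12 with a correlation of 0.05). Oocyte markers had 0 raised and 22 lowered of 24 (adjusted over the list alone 0 and 22, median -0.38, adjusted p = 4.8e-04). Early zygotic markers had 1 raised and 9 lowered of 19 (adjusted over the list alone 1 and 9, median -0.69, adjusted p = 0.063). Sperm genes had 5 raised and 0 lowered of 43 (adjusted over the list alone 0 and 0, median 1.55, adjusted p = 0.33). Examples of the authors' deposited table are the myosins myo-3 (1.49 ± 0.11) and myo-2 (1.03 ± 0.11), the neuropeptide enzyme egl-3 (0.64 ± 0.08), the intestinal filament ifb-2 (1.05 ± 0.09), the oocyte gene puf-3 (-0.68 ± 0.10) and the embryonic gene pes-10 (-1.17 ± 0.14).

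Proteasome subunits had 0 raised and 31 lowered of 32 (adjusted over the list alone 0 and 31, median -0.51, adjusted p = 4.0e-08). Ribosomal proteins had 3 raised and 49 lowered of 78 (adjusted over the list alone 3 and 51, median -0.26, adjusted p = 1.2e-04). Vitellogenins had 0 raised and 3 lowered of 6, 2 without a p-value (adjusted over the list alone 0 and 3, median -0.79, adjusted p = 0.01). The authors' deposited table lists vit-3 (-1.57 ± 0.14) and vit-1 (-0.99 ± 0.11) as lowered, and without a p-value vit-2 (1214 to 1268 TPM) and vit-6 (1635 to 1687 TPM), which the median leaves out. Pathogen response genes had 7 raised and 6 lowered of 16 (adjusted over the list alone 7 and 6, median 0.29, adjusted p = 0.0092), and the authors' deposited table shows dod-24 lowered (-5.17, listed with q = 0), C17H12.8 (-2.63 ± 0.14) lowered and F08G5.6 (2.74 ± 0.11) raised. Lysosomal proteases had 5 raised and 4 lowered of 11 (adjusted over the list alone 5 and 4, median -0.02, adjusted p = 0.01). The authors' deposited table has cpr-4 (1.97 ± 0.09) and cpr-1 (1.64 ± 0.08) as raised. P450 genes had 30 raised and 10 lowered of 62 (adjusted over the list alone 30 and 10, median 0.77, adjusted p = 0.0033, or adjusted p = 0.09 with a correlation of 0.05). UDP-glucuronosyltransferases had 27 raised and 8 lowered of 60 (adjusted over the list alone 27 and 8, median 0.69, adjusted p = 0.01, or adjusted p = 0.14 with a correlation of 0.05). The authors' deposited table gives cyp-13A5 (3.13 ± 0.12) and ugt-21 (2.48 ± 0.21) as raised. SKN-1 detoxification targets had 5 raised and 7 lowered of 17 (adjusted over the list alone 5 and 7, median -0.23, adjusted p = 0.084), where the authors' deposited table gives gst-5 (0.71 ± 0.10) raised and gst-38 (-4.92 ± 0.18) and gst-13 (-0.93 ± 0.09) lowered.

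The set test did not pass for trehalases (2 and 1 of 5), aquaporins (2 and 2 of 11), glutathione S-transferases (15 and 6 of 37) and heat shock proteins (1 and 3 of 18). Nor did it pass for ER unfolded protein response genes (2 and 2 of 13), mitochondrial chaperones (0 and 3 of 4), DAF-16 targets (4 and 1 of 11) and fatty acid metabolism (7 and 5 of 20). It also missed the threshold for glucose and glycogen metabolism (7 and 4 of 19) and histones (4 and 22 of 44). Adjusted p of these lists lay from 0.06 to 1. Adjusted over the list alone, these counts were histones (4 and 23) and otherwise unaltered. Median and test had opposite signs for trehalases (0.14, test down), other named cuticle collagens (-1.63, test up), pathogen response genes (0.29, test down), lysosomal proteases (-0.02, test up) and fatty acid metabolism (-0.12, test up). The call did not hold against random lists for osmotic response regulators (0.12), UDP-glucuronosyltransferases (0.061), lysosomal proteases (0.08), cytosolic ribosomal proteins (0.46), oocyte and eggshell markers (0.32), intestine markers (0.061) and neuron markers (0.086). Of the random lists 79.3% had a median at or below that of ribosomal proteins and 98.95% at or below that of pathogen response genes (adjusted p = 0.04), both against the direction of the set test. Equal total TPM adds 0.17 to each log2 change here and turns the medians of ER genes, lysosomal proteases and fatty acid metabolism positive. It leaves ribosomal proteins at -0.09, oocyte markers at -0.21 and proteasome subunits at -0.34.

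**Figure D1:**
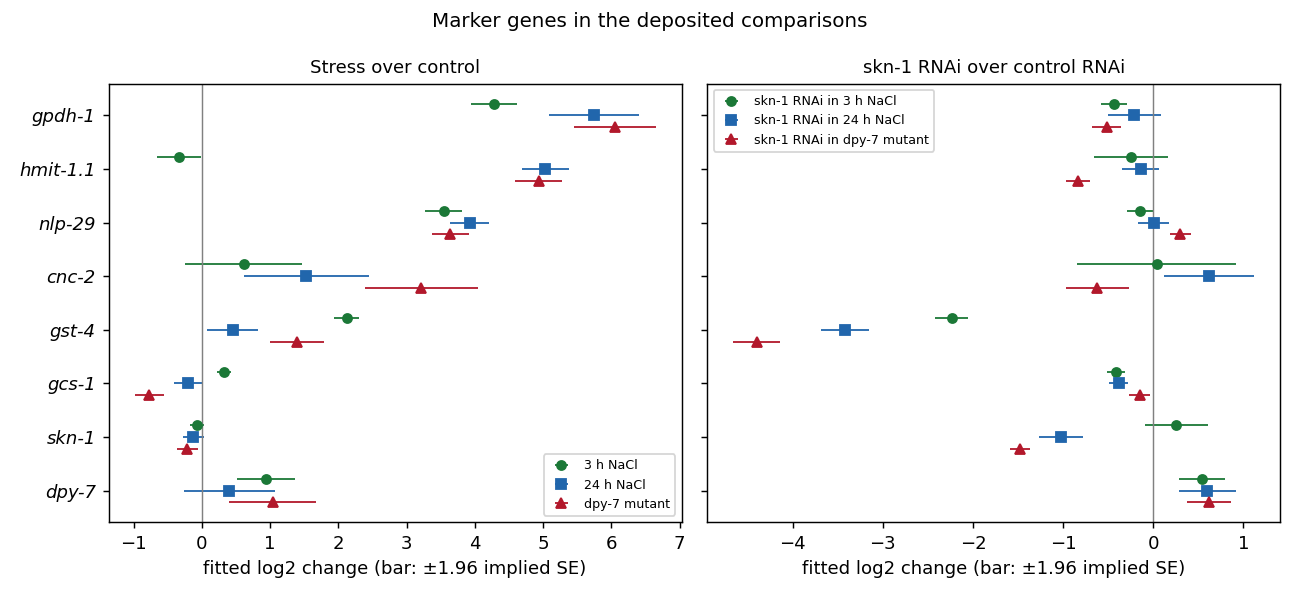
Fitted log2 change of 8 marker genes from the authors' deposited tables, with bars of 95% intervals from the implied standard errors, for stress over control in one panel and skn-1 RNAi over control RNAi in the other. Under stress gpdh-1 lies at 4.27, 5.74 and 6.05, and with skn-1 RNAi gst-4 lies at -2.24, -3.42 and -4.40.

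Called genes of the stress comparisons overlapped. Of 14412 genes tested in both, 2163 rose at 24 h of salt and in dpy-7, where independent calls would give 855.7 (odds ratio 12.2), and 2650 fell in both against 1079. Opposite calls were 96 and 74. The log2 changes correlated across genes (Pearson r = 0.764), and genes are not independent replicates. Both comparisons use the same control group, whose error alone gave r = 0.492 in simulations. That r, of error without effects, cannot be set against 0.764. Such error gave 26 shared raised genes at the called p and 0 after adjustment. The 3 h comparison has its own control. It shared 1336 raised genes with dpy-7 of 13960 (636.6 if independent, 1-sided Fisher's exact p = 5.5e-253) and 1531 lowered genes (858.7), with 156 and 349 called in opposite directions. It shared 1382 raised genes with 24 h of 14036 (514.6 if independent, odds ratio 8.46) and 1547 lowered genes (643.8). All 3 comparisons raised 1007 and lowered 1238 of 13829 genes.

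**Figure D2:**
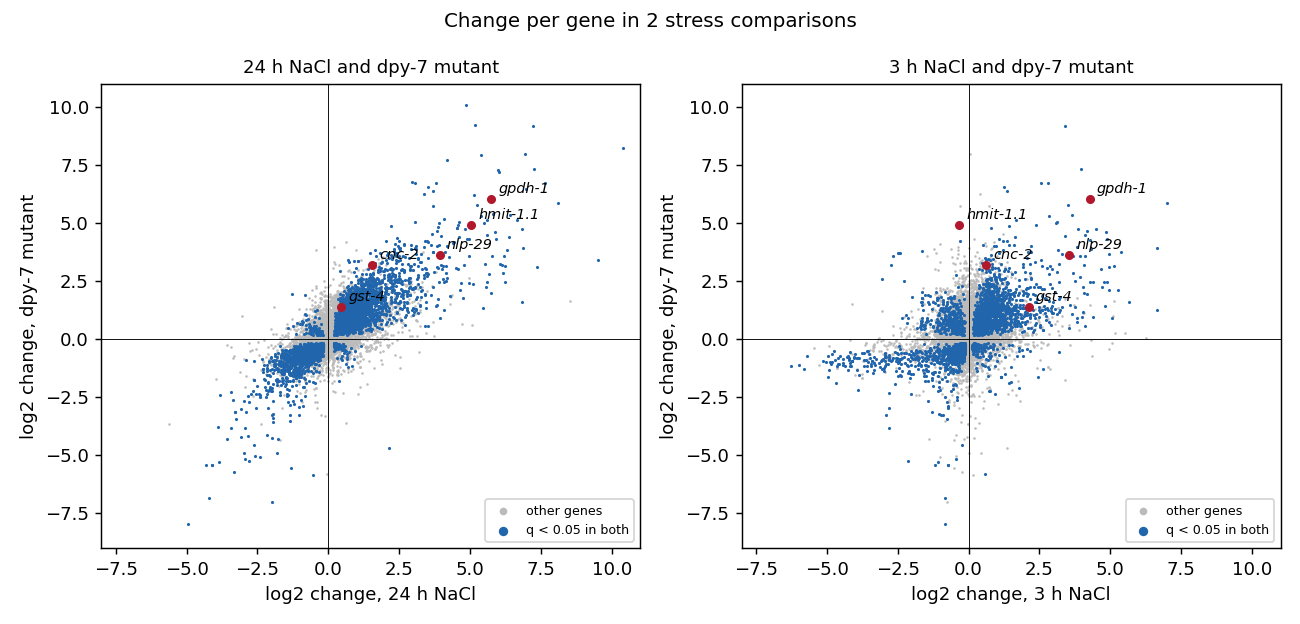
Log2 change per gene in the dpy-7 mutant against 24 h NaCl, which share a control, and against 3 h NaCl, which has its own; blue points have q below 0.05 in both. Genes raised in both number 2163 and 1336.

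The skn-1 RNAi comparisons ask which stressed transcript levels depend on skn-1, each against the group of equal stress with control RNAi. The targeted gene itself was not lowered in the libraries labelled skn-1 RNAi at 3 h, where the authors' deposited table gives skn-1 (27.4 to 33.6 TPM, 0.26 ± 0.18, q = 0.62). Its listed level in the stressed control libraries departs by 23.8% from that in the salt table. Target genes of SKN-1 were lower all the same, as the authors' deposited table shows for gst-4 (143 to 30.2 TPM, -2.24 ± 0.09) and gcs-1 (-0.41 ± 0.05). Of the osmolyte genes in the authors' deposited table, gpdh-1 (146 to 108 TPM, -0.43 ± 0.07) fell, and hmit-1.1 (-0.25 ± 0.21, q = 0.72) did not pass. Peptide genes nlp-29 (-0.14 ± 0.07, q = 0.37) and cnc-2 (0.04 ± 0.45, q = 0.99) did not pass in the authors' deposited table, and dpy-7 (0.54 ± 0.13) rose. In all 300 genes rose and 578 fell of 14601, with 17 and 90 changed more than 2-fold, all in libraries whose skn-1 level was not lowered.

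In these 3 h libraries the authors' deposited table gives the largest falls as dod-24 (-4.74 ± 1.05), the glucuronosyltransferase gene ugt-57 (-3.58 ± 0.39), ttr-52 (-3.49 ± 0.93), the aspartic protease gene asp-14 (-3.17 ± 0.35) and gst-4. The largest rises of the authors' deposited table were ech-1.1 (1.52 ± 0.21), cyp-13B1, cyp-13B2 (1.23 ± 0.17), lact-5 (whose level in the same libraries differs by over 10 percent between tables) and the collagen sqt-1 (1.02 ± 0.21).

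Of the SKN-1 detoxification targets, 0 of 16 measured members rose, 9 fell and 7 did not pass the test (adjusted over the list alone, 0 rose and 10 fell), with median log2 change -0.76 and adjusted p = 2.8e-34. Glutathione S-transferases had 0 raised and 7 lowered of 33 (adjusted over the list alone 0 and 8, median -0.26, adjusted p = 2.1e-13). UDP-glucuronosyltransferases had 1 raised and 15 lowered of 58 (adjusted over the list alone 2 and 18, median -0.27, adjusted p = 4.2e-11). The authors' deposited table shows gst-13 (-1.69 ± 0.11), gst-10 (-0.96 ± 0.12), ugt-13 (-1.48 ± 0.14) and ugt-22 (-1.01 ± 0.06) as lowered. Proteasome subunits had 0 raised and 25 lowered of 32 (adjusted over the list alone 0 and 30, median -0.23, adjusted p = 7.0e-37). The authors' deposited table lists rpn-3 (-0.37 ± 0.04) and pas-3 (-0.30 ± 0.04) as lowered. Osmolyte genes had 0 raised and 5 lowered of 11 (adjusted over the list alone 0 and 5, median -0.20, adjusted p = 1.8e-07). The authors' deposited table has C53A3.2 (-0.54 ± 0.07), F44E7.2 (-0.39 ± 0.06) and K09H11.7 (-0.62 ± 0.14) as lowered. Pathogen response genes had 0 raised and 8 lowered of 15 (adjusted over the list alone 0 and 10, median -0.46, adjusted p = 2.0e-13). The authors' deposited table gives F35E12.5 (-1.62 ± 0.22) and the lysozyme gene lys-7 (-0.73 ± 0.09) as lowered. Fatty acid genes had 1 raised and 8 lowered of 20 (adjusted over the list alone 2 and 9, median -0.25, adjusted p = 1.8e-07). Other cuticle collagens had 5 raised and 0 lowered of 13 (adjusted over the list alone 8 and 0, median 0.69, adjusted p = 2.5e-16). Furrow collagens had 2 raised and 0 lowered of 6 (adjusted over the list alone 4 and 0, median 0.35, adjusted p = 4.3e-05). Molting genes had 6 raised and 0 lowered of 23 (adjusted over the list alone 6 and 1, median 0.09, adjusted p = 4.1e-06). The authors' deposited table lists dpy-14 (0.79 ± 0.05), dpy-17 (0.69 ± 0.06), noah-1 (0.85 ± 0.10) and noah-2 (0.77 ± 0.07) as raised.

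Intestine markers had 0 raised and 7 lowered of 11 (adjusted over the list alone 0 and 7, median -0.25, adjusted p = 3.7e-11). Muscle markers had 6 raised and 0 lowered of 16 (adjusted over the list alone 8 and 0, median 0.14, adjusted p = 4.0e-06). Epidermis markers had 4 raised and 1 lowered of 15 (adjusted over the list alone 5 and 1, median 0.05, adjusted p = 0.049, or adjusted p = 0.13 with a correlation of 0.05) in the same libraries. The intestinal transcription factor elt-2 (-0.80 ± 0.15) and pgp-1 (-0.97 ± 0.08) were lowered in the authors' deposited table. Sperm genes had 3 raised and 0 lowered of 60 (adjusted over the list alone 3 and 0, median 0.19, adjusted p = 2.9e-04). Histones had 0 raised and 3 lowered of 54 (adjusted over the list alone 0 and 2, median -0.47, adjusted p = 0.0074, or adjusted p = 0.11 with a correlation of 0.05). Ribosomal proteins had 0 raised and 0 lowered of 79 (adjusted over the list alone 0 and 0, median 0.04, adjusted p = 0.011, or adjusted p = 0.15 with a correlation of 0.05). Antimicrobial peptides had 0 raised and 0 lowered of 17 (adjusted over the list alone 0 and 0, median -0.24, adjusted p = 0.015, or adjusted p = 0.07 with a correlation of 0.05). Osmotic regulators had 3 raised and 1 lowered of 12 (adjusted over the list alone 4 and 1, median 0.11, adjusted p = 0.049, or adjusted p = 0.11 with a correlation of 0.05). Lysosomal proteases had 2 raised and 2 lowered of 11 (adjusted over the list alone 2 and 3, median -0.04, adjusted p = 0.048, or adjusted p = 0.11 with a correlation of 0.05). Trehalases had 0 raised and 1 lowered of 5 (adjusted over the list alone 0 and 1, median -0.18, adjusted p = 0.041, or adjusted p = 0.07 with a correlation of 0.05).

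The set test did not pass for aquaporins (1 and 1 of 11), cytochrome P450s (6 and 6 of 60), numbered collagens (6 and 2 of 114) and heat shock proteins (0 and 2 of 17). Nor did it pass for ER unfolded protein response genes (1 and 2 of 13), mitochondrial chaperones (0 and 0 of 4), DAF-16 targets (2 and 0 of 10) and vitellogenins (0 and 0 of 6). It also missed the threshold for glucose and glycogen metabolism (0 and 2 of 20), oocyte and eggshell markers (0 and 0 of 24), early embryo zygotic markers (0 and 0 of 8) and neuron markers (0 and 0 of 17). Adjusted p of these lists lay from 0.21 to 0.88. Adjusted over the list alone, these counts were aquaporins (1 and 2), cytochrome P450s (6 and 9), numbered collagens (8 and 2), DAF-16 targets (2 and 1), glucose and glycogen metabolism (2 and 2) and otherwise unaltered. Median and test had opposite signs for numbered collagens (-0.07, test up), DAF-16 targets (-0.08, test up), lysosomal proteases (-0.04, test up) and neuron markers (-0.01, test up). Against random lists the call was lost for trehalases (0.11), osmotic response regulators (0.11), molting and hedgehog-related genes (0.11), lysosomal proteases (0.16) and epidermis markers (0.35); 5.46% had a median as low as lysosomal proteases, whose set test is up.

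At 24 h of salt the authors' deposited table shows a lowered target, skn-1 (25.9 to 12.7 TPM, -1.02 ± 0.12, q = 1.1e-14). The detoxification genes gst-4 (119.8 to 11.1 TPM, -3.42 ± 0.13) and gcs-1 (-0.38 ± 0.05) fell with it in the authors' deposited table. The osmolyte genes gpdh-1 (-0.21 ± 0.15, q = 0.33) and hmit-1.1 (-0.14 ± 0.10, q = 0.36) and the peptide genes nlp-29 (0.01 ± 0.09, q = 0.96) and cnc-2 (0.62 ± 0.26, q = 0.06) of the authors' deposited table did not pass, the last with an adjusted p of 0.049 at equal total TPM. The collagen gene dpy-7 (0.60 ± 0.16) rose in the authors' deposited table. Over all genes 1653 rose and 1984 fell of 14841, with 140 and 615 changed more than 2-fold. Equal total TPM gave 1977 and 1878, and leaving out the lowest 25 percent of abundance 1625 and 1552.

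Largest among the falls of the authors' deposited table were dod-24 (73.5 to 0.339 TPM, -7.49 ± 0.86), the pharyngeal gland gene phat-5 (-7.24 ± 0.54), the collagen col-117 (-6.76 ± 2.41), pqn-71 (-5.40 ± 0.65) and asp-14 (-5.35 ± 0.54). Largest among its rises were oac-57 (2.30 ± 0.83), the cuticulin genes cut-5 (1.71 ± 0.25) and cutl-2 (1.57 ± 0.18), and dsl-3 (1.63 ± 0.18) and dsl-6 (1.58 ± 0.19) of a family of Notch ligands, again from the authors' deposited table.

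SKN-1 detoxification targets had 0 raised and 14 lowered of 16 (adjusted over the list alone 0 and 14, median -1.32, adjusted p = 1.1e-26). The authors' deposited table gives nit-1 (-2.39 ± 0.19), gst-10 (-1.82 ± 0.13) and gst-5 (-1.73 ± 0.09) as lowered. Glutathione S-transferases had 0 raised and 14 lowered of 37 (adjusted over the list alone 1 and 18, median -0.60, adjusted p = 1.5e-11). UDP-glucuronosyltransferases had 1 raised and 20 lowered of 58 (adjusted over the list alone 3 and 22, median -0.33, adjusted p = 2.9e-06). Proteasome subunits had 0 raised and 27 lowered of 32 (adjusted over the list alone 1 and 27, median -0.25, adjusted p = 1.2e-19). Ribosomal proteins had 0 raised and 60 lowered of 78 (adjusted over the list alone 0 and 65, median -0.20, adjusted p = 2.3e-21). The authors' deposited table lists rpn-3 (-0.42 ± 0.04) and rpl-11.2 (-0.56 ± 0.08) as lowered. Pathogen response genes had 2 raised and 10 lowered of 16 (adjusted over the list alone 2 and 11, median -0.57, adjusted p = 6.7e-06). DAF-16 targets had 0 raised and 4 lowered of 12 (adjusted over the list alone 0 and 4, median -0.27, adjusted p = 0.01). In the authors' deposited table these include F08G5.6 (-2.09 ± 0.15), irg-2 (-1.16 ± 0.14), mtl-1 (-1.49 ± 0.15), dod-3 (-1.07 ± 0.20) and ftn-1 (-0.98 ± 0.21). Osmolyte genes had 1 raised and 3 lowered of 11 (adjusted over the list alone 1 and 4, median -0.17, adjusted p = 0.068). The authors' deposited table has the trehalose synthases tps-1 (-0.33 ± 0.08) and tps-2 (-0.37 ± 0.11) as lowered.

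Muscle markers had 0 raised and 12 lowered of 16 (adjusted over the list alone 0 and 12, median -0.35, adjusted p = 5.9e-12). Neuron markers had 0 raised and 14 lowered of 17 (adjusted over the list alone 1 and 14, median -0.65, adjusted p = 3.8e-13). Intestine markers had 0 raised and 8 lowered of 11 (adjusted over the list alone 0 and 9, median -0.44, adjusted p = 1.3e-08). Examples of the authors' deposited table are myo-2 (-1.09 ± 0.12), tni-1 (-0.87 ± 0.10), rab-3 (-1.27 ± 0.14), egl-3 (-0.65 ± 0.06) and ifb-2 (-0.81 ± 0.06), all lowered. Oocyte markers had 10 raised and 0 lowered of 24 (adjusted over the list alone 12 and 0, median 0.11, adjusted p = 8.2e-05). Early zygotic markers had 3 raised and 2 lowered of 17 (adjusted over the list alone 4 and 2, median 0.05, adjusted p = 0.4). In the authors' deposited table the embryonic gene vet-2 (0.78 ± 0.11) rose and the mesoderm gene ceh-51 (-1.40 ± 0.53) fell. Molting genes had 8 raised and 4 lowered of 23 (adjusted over the list alone 8 and 4, median 0.16, adjusted p = 0.025, or adjusted p = 0.12 with a correlation of 0.05). The authors' deposited table gives noah-1 (0.88 ± 0.07) and ptr-4 (1.16 ± 0.12) as raised and grd-13 (-2.63 ± 0.27) as lowered. Other cuticle collagens had 3 raised and 8 lowered of 13 (adjusted over the list alone 3 and 8, median -1.99, adjusted p = 0.11). Furrow collagens had 4 raised and 2 lowered of 6 (adjusted over the list alone 4 and 2, median 0.58, adjusted p = 0.29). The authors' deposited table shows dpy-17 (1.28 ± 0.07) and dpy-14 (1.32 ± 0.08) as raised and dpy-8 (-3.44 ± 0.47) and sqt-2 (-2.44 ± 0.54) as lowered.

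The set test did not pass for trehalases (1 and 1 of 5), aquaporins (1 and 3 of 11), osmotic response regulators (0 and 2 of 12), cytochrome P450s (7 and 15 of 64), epidermal antimicrobial peptides (2 and 1 of 18) and numbered collagens (25 and 34 of 129). Nor did it pass for heat shock proteins (1 and 2 of 18), ER unfolded protein response genes (2 and 0 of 13), mitochondrial chaperones (0 and 1 of 4), vitellogenins (3 and 0 of 6), lysosomal proteases (4 and 4 of 11) and fatty acid metabolism (4 and 4 of 20). It also missed the threshold for glucose and glycogen metabolism (3 and 3 of 20), histones (0 and 8 of 46), sperm markers (0 and 0 of 51) and epidermis markers (5 and 3 of 15). Adjusted p of these lists lay from 0.088 to 0.78. Adjusted over the list alone, these counts were cytochrome P450s (7 and 17), numbered collagens (27 and 38), lysosomal proteases (5 and 5), glucose and glycogen metabolism (4 and 3) and otherwise unaltered. Median and test had opposite signs for trehalases (0.06, test down), other named cuticle collagens (-1.99, test up), ER unfolded protein response genes (-0.02, test up) and glucose and glycogen metabolism (-0.01, test up). The call of oocyte and eggshell markers (0.055) was lost against random lists.

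In dpy-7 the target fell, as the authors' deposited table gives skn-1 (25.6 to 9.15 TPM, -1.48 ± 0.06, q = 8.8e-154), and gst-4 (243 to 11.4 TPM, -4.40 ± 0.13) fell with it. Osmolyte genes hmit-1.1 (55.1 to 30.7 TPM, -0.84 ± 0.07) and gpdh-1 (76.5 to 53.2 TPM, -0.52 ± 0.08) were also lowered in the authors' deposited table. Of the peptide genes, nlp-29 (541 to 661 TPM, 0.30 ± 0.06) rose and cnc-2 (76.2 to 48.8 TPM, -0.62 ± 0.18) fell in the authors' deposited table. There gcs-1 (-0.15 ± 0.06, q = 0.052) did not pass, and dpy-7 (0.62 ± 0.13) rose. Over all genes 1317 rose and 2036 fell of 14862, with 141 and 599 changed more than 2-fold.

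Falls were largest in the authors' deposited table for dod-24 (-5.58 ± 0.67), nspa-8 (-5.06 ± 0.72), nspb-11 and fipr-8 (both listed at 0 with skn-1 RNAi) and nspb-6 (-4.55 ± 0.80). Rises were largest in the authors' deposited table for the astacin protease gene nas-10 (2.52 ± 0.27), the collagen col-150 (2.18 ± 0.24), the protease gene adt-1 (2.02 ± 0.32), eol-1 (1.97 ± 0.42) and cyp-25A1 (1.72 ± 0.23).

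SKN-1 detoxification targets had 0 raised and 11 lowered of 16 (adjusted over the list alone 0 and 13, median -1.22, adjusted p = 5.7e-25). Glutathione S-transferases had 0 raised and 18 lowered of 36 (adjusted over the list alone 1 and 21, median -0.88, adjusted p = 5.5e-20). The authors' deposited table lists gst-10 (-2.37 ± 0.11), gst-24 (-1.93 ± 0.12), gst-13 (-1.73 ± 0.11) and gst-5 (-1.57 ± 0.11) as lowered. UDP-glucuronosyltransferases had 4 raised and 16 lowered of 59 (adjusted over the list alone 4 and 17, median -0.31, adjusted p = 0.0099, or adjusted p = 0.14 with a correlation of 0.05). Proteasome subunits had 0 raised and 27 lowered of 32 (adjusted over the list alone 0 and 27, median -0.25, adjusted p = 9.2e-13). Lysosomal proteases had 1 raised and 9 lowered of 11 (adjusted over the list alone 2 and 9, median -0.36, adjusted p = 1.1e-11). The authors' deposited table gives rpt-6 (-0.50 ± 0.06), cpr-5 (-0.86 ± 0.05) and cpr-1 (-0.72 ± 0.05) as lowered. Pathogen response genes had 2 raised and 9 lowered of 17 (adjusted over the list alone 2 and 9, median -0.42, adjusted p = 1.7e-06). The authors' deposited table shows lys-7 (1476 to 564 TPM, -1.38 ± 0.09) and F08G5.6 (-1.56 ± 0.10) as lowered. DAF-16 targets had 0 raised and 5 lowered of 12 (adjusted over the list alone 0 and 7, median -0.55, adjusted p = 0.011). Antimicrobial peptides had 6 raised and 2 lowered of 18 (adjusted over the list alone 7 and 2, median 0.01, adjusted p = 0.032, or adjusted p = 0.12 with a correlation of 0.05). The authors' deposited table has nlp-30 (1.62 ± 0.30), nlp-33 (1.01 ± 0.14) and cnc-4 (0.92 ± 0.10) as raised. Osmolyte genes had 1 raised and 4 lowered of 11 (adjusted over the list alone 2 and 5, median -0.19, adjusted p = 0.066).

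Muscle markers had 0 raised and 12 lowered of 16 (adjusted over the list alone 0 and 13, median -0.47, adjusted p = 5.1e-20). Neuron markers had 0 raised and 6 lowered of 17 (adjusted over the list alone 0 and 7, median -0.36, adjusted p = 6.8e-04). Intestine markers had 0 raised and 8 lowered of 11 (adjusted over the list alone 0 and 8, median -0.68, adjusted p = 1.0e-13). Lowered in the authors' deposited table were the pharyngeal myosins myo-2 (-2.14 ± 0.08) and myo-1 (-1.89 ± 0.10), egl-3 (-0.69 ± 0.07) and ifc-2 (-0.89 ± 0.06). Oocyte markers had 5 raised and 0 lowered of 24 (adjusted over the list alone 5 and 0, median 0.09, adjusted p = 0.0079, or adjusted p = 0.062 with a correlation of 0.05). Early zygotic markers had 3 raised and 3 lowered of 17 (adjusted over the list alone 4 and 3, median 0.06, adjusted p = 0.41). Molting genes had 12 raised and 2 lowered of 23 (adjusted over the list alone 13 and 2, median 0.35, adjusted p = 3.9e-05). Other cuticle collagens had 3 raised and 8 lowered of 13 (adjusted over the list alone 3 and 9, median -1.72, adjusted p = 0.0021). The authors' deposited table shows ptr-4 (0.94 ± 0.14) and wrt-10 (0.72 ± 0.08) as raised and rol-6 (-2.03 ± 0.24) and dpy-8 (-2.22 ± 0.23) as lowered.

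The set test did not pass for trehalases (0 and 2 of 5), aquaporins (0 and 4 of 11), osmotic response regulators (2 and 2 of 12), cytochrome P450s (9 and 10 of 66), annular furrow collagens (3 and 2 of 6) and numbered collagens (24 and 35, with 60 not past the test). Nor did it pass for heat shock proteins (4 and 1 of 18), ER unfolded protein response genes (1 and 4 of 13), mitochondrial chaperones (0 and 2 of 4), vitellogenins (2 and 0 of 6), fatty acid metabolism (2 and 5 of 20) and glucose and glycogen metabolism (0 and 5 of 20). It also missed the threshold for cytosolic ribosomal proteins (1 and 4 of 78), histones (1 and 3 of 30), sperm markers (0 and 0 of 41) and epidermis markers (5 and 3 of 15). Adjusted p of these lists lay from 0.11 to 0.94. Adjusted over the list alone, these counts were trehalases (0 and 3), cytochrome P450s (10 and 12), numbered collagens (24 and 37), vitellogenins (3 and 0), cytosolic ribosomal proteins (1 and 3), epidermis markers (6 and 3) and otherwise unaltered. Median and test had opposite signs for fatty acid metabolism (-0.05, test up). The call of epidermal antimicrobial peptides (0.72) was lost against random lists, 36.2% of which had a median as low.

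**Figure D3:**
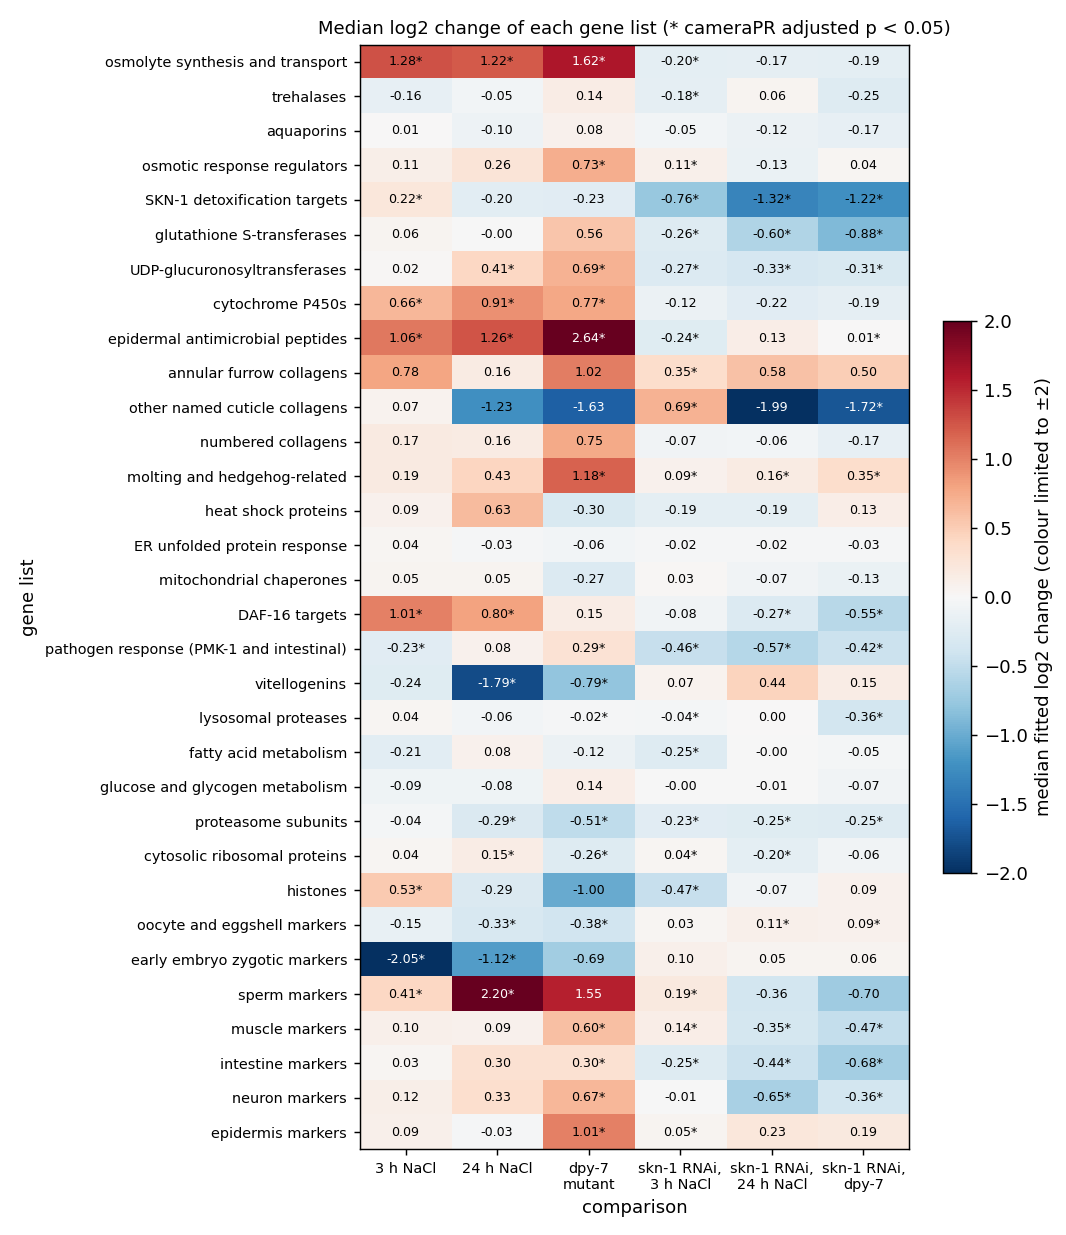
Median log2 change of the 32 lists in the 6 comparisons, with colour limited to 2 in either direction and an asterisk for cameraPR adjusted p below 0.05. SKN-1 detoxification targets lie at -0.76, -1.32 and -1.22 with skn-1 RNAi, and antimicrobial peptides at 1.06, 1.26 and 2.64 under stress.

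Genes raised by stress were then looked up in the knockdown. Of those raised at 3 h, 217 of 2528 (8.58%) were lower with the RNAi at that time, although skn-1 itself was not lowered there. Abundance-matched genes that did not rise gave 3.28% (95% of draws from 2.65% to 3.96%). At 24 h 968 of 3248 raised genes (29.8%) were lower with skn-1 RNAi, against 9.95% of matched genes (8.96% to 10.9%). In dpy-7 these were 1369 of 4167 (32.9%), against 6.84% (6.05% to 7.63%). Matching was for abundance alone. Muscle, neuron and intestine markers fell and oocyte markers rose with the RNAi at 24 h and in dpy-7. So a shift in tissue shares, which was not tested, stays open. The stressed control-RNAi group enters both comparisons with opposite sign. Its error alone gave shares of 0.282%, 0.935% and 0.792% in simulations. Raised genes that were higher with skn-1 RNAi numbered 147, 192 and 371. The fall with skn-1 RNAi exceeded 50% of the rise for 123, 597 and 979 genes. In the authors' deposited table gpdh-1 fell by -0.43 at 3 h against a rise of 4.27, and by -0.52 in dpy-7 against 6.05.

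**Figure D4:**
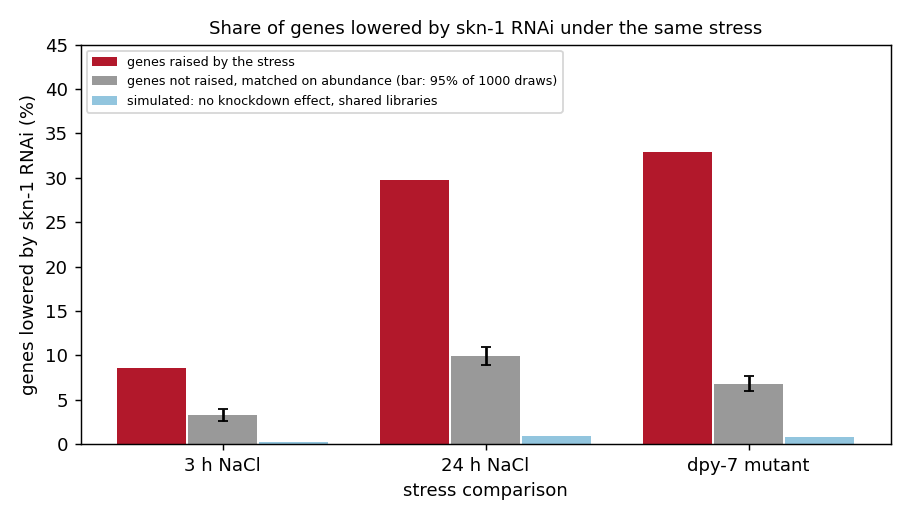
Share of genes lowered by skn-1 RNAi, in percent, among genes raised by each stress, among matched genes not raised (bar with 95% of 1000 draws) and in simulations of the shared group. Raised genes reach 8.58%, 29.8% and 32.9%, and matched genes 3.28%, 9.95% and 6.84%.

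Among genes lowered by stress, 161 of 2493 (6.46%) were lower still with skn-1 RNAi at 3 h and 37 (1.48%) were higher, as were 2.18% of genes not lowered. At 24 h 156 of 3389 were lower still and 1016 were higher (against 5.67% of genes not lowered). In dpy-7 166 of 4488 (3.70%) were lower still and 704 (15.7%, against 5.84%) were higher. Genes lowered by the RNAi were shared between the 24 h and dpy-7 comparisons in 1121 cases (270 if independent), and 590 were raised in both. The 3 h comparison shared 290 lowered genes with 24 h (78.0 if independent) and 305 with dpy-7 (80.5). All 3 lowered 230 and raised 84 of 13439 genes. Among the genes lowest in all 3 in the authors' deposited table, a choice made after their values were seen, were dod-24 (-4.74, -7.49 and -5.58), ugt-57 (-3.58, -3.68 and -3.22), asp-14 (-3.17, -5.35 and -3.13), nit-1 (-2.04, -2.39 and -2.77) and the pharyngeal regulator ceh-22 (-1.41, -1.23 and -2.30).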

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

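The tests of swapped or missing knockdown, other skn-1 transcripts, germline content and embryo share were chosen only after the results they address had been seen. So was the need for a list to differ at both preset correlations.

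The results in this part are differences between comparisons of the same kind, each with an adjusted p below 0.05. Over all genes the change under salt differed between 24 h and 3 h for 3134 of 14036. The change with skn-1 RNAi differed between 24 h and 3 h for 1454 of 13789, between dpy-7 and 24 h for 546 of 14262, and between dpy-7 and 3 h for 1317 of 13563. Values are differences of log2 changes for single genes of the authors' deposited tables, and for a list their median over its members.

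Under salt, 24 h exceeded 3 h by 1.47 for gpdh-1 and 5.36 for hmit-1.1, and gave -1.67 for gst-4 and -0.53 for gcs-1. The median difference of list members was -0.21 for proteasome subunits, -0.55 for SKN-1 detoxification targets and -1.38 for vitellogenins.

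With skn-1 RNAi under salt, 24 h minus 3 h gave -1.28 for skn-1 and -1.18 for gst-4. Lists gave -0.24 for ribosomal proteins, -0.48 for muscle markers, -0.64 for neuron markers and -0.39 for SKN-1 detoxification targets.

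With skn-1 RNAi, dpy-7 minus 24 h of salt gave -0.46 for skn-1, -0.70 for hmit-1.1, -0.98 for gst-4, 0.23 for gcs-1, 0.29 for nlp-29 and -1.24 for cnc-2. Lists gave 0.14 for ribosomal proteins, -0.39 for lysosomal proteases, -0.17 for muscle markers and 0.29 for neuron markers.

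Between dpy-7 and 3 h the RNAi effects differed by -1.74 for skn-1, -0.59 for hmit-1.1, -2.16 for gst-4, 0.26 for gcs-1 and 0.44 for nlp-29. Lists gave -0.45 for DAF-16 targets, 0.49 for antimicrobial peptides, 0.20 for fatty acid metabolism, -0.31 for glutathione S-transferases, -0.20 for intestine markers, -0.28 for lysosomal proteases, -0.57 for muscle markers, -0.33 for neuron markers, -1.86 for other named cuticle collagens and -0.35 for SKN-1 detoxification targets.

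The level of skn-1 was not lowered in the libraries labelled skn-1 RNAi at 3 h, where the authors' deposited table gives 0.26 ± 0.18. Swapped libraries or a knockdown that did not take would leave the SKN-1 targets level or raised, and their median of -0.762 argues against both. A candidate explanation is that other skn-1 transcripts were summed in this table than in the salt table, since the listed skn-1 level of the same libraries departs by 23.8%; it also departs by -19.9% between the tables at 24 h, where the authors' deposited table has skn-1 lowered by the RNAi, so a departure alone need not hide a knockdown. Such departures were found in 0.724% of single-transcript genes and 11.3% of genes with several transcripts, in line with transcripts kept separately for each table. Which transcripts were kept is not given in the sources used here, so this stays open, as does a knockdown at the protein level without loss of the RNA, which was not tested.

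Proteasome subunits were lower with skn-1 RNAi in all 3 comparisons, the 3 h libraries without lowered skn-1 included, with medians of -0.23, -0.25 and -0.25. An offset in scaling would move random lists alike, and 0 of 10000 random lists of equal size and abundance had a median as low in any of the 3. Less germline in the knockdown libraries would lower oocyte genes as well, and these lay above the proteasome by 0.261 at the smallest. Both values argue against these; intestine markers fell in the same comparisons, with medians of -0.25, -0.44 and -0.68, while vitellogenins, made in the intestine, had 0.07, 0.44 and 0.15. So less intestinal RNA, which was not tested, stays open beside a dependence of proteasome genes on SKN-1, a hypothesis found and tested on the same data.

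Genes raised in both 24 h of salt and dpy-7 share a control group. The covariance of both effects was 10.97 times that simulated from sampling error of the shared control alone, which argues against such error as the source of the overlap. The simulation holds only the implied errors and cannot show whether the whole control group was unusual, which was not tested. A lower share of embryos or germline might lift all other tissues. The shared raised genes exceeded the highest median of the adult tissue markers by 0.639 at 24 h and 0.222 in dpy-7, but genes chosen as raised lie above unselected markers whatever the cause, so neither value decides. This explanation stays open for both, as does a common response to salt and to the mutated furrow collagen.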

How the results depend on the processing

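Later alternatives here are those chosen only after the data were seen. Of the 8 genes named in each comparison, none called changed reversed its direction with equal total TPM. The majority of changed genes turned from lowered to raised with equal total TPM at 24 h (3989 and 2272), in dpy-7 (5024 and 2534) and with RNAi at 24 h (1977 and 1878), and some list medians turned positive. It also turned without the lowest 25 percent of abundance with RNAi at 24 h (1625 and 1552), at q below 0.01 at 3 h (1906 and 1826), and above an absolute log2 change of 1 at 3 h, 24 h and in dpy-7. Of the main counts, 49 of those under alternatives fixed beforehand stayed within 1.5 times, 16 fell below and 1 rose above; all 18 under later alternatives stayed within. For these 8 genes 47 and 46 calls were kept under earlier and later alternatives, and 3 were not: skn-1 in dpy-7 (equal total TPM, -0.04, adjusted p = 0.67), cnc-2 with RNAi at 24 h (equal total TPM, 0.64, adjusted p = 0.049) and gcs-1 with RNAi in dpy-7 (lowest 25 percent left out, -0.15, adjusted p = 0.046). With an absolute log2 change over 1, genes changed numbered 1504, 2196 and 2767 for 3 h, 24 h and dpy-7 and 107, 755 and 740 with RNAi. Shared raised genes then numbered 416 (3 h and 24 h), 882 (24 h and dpy-7) and 366 (3 h and dpy-7), and raised genes lower with RNAi 100, 435 and 707; the stricter requirement itself leaves fewer genes. At q below 0.01 the counts were 2338 with RNAi at 24 h, 2219 with RNAi in dpy-7, and 599 raised genes lower with RNAi at 24 h, again from the stricter threshold. Called lists at 3 h of salt rose from 9 to 14 against random lists, and with RNAi at 3 h fell from 20 to 13 with a correlation of 0.05; the cause was not tested. A normal p from effect and standard error was not run, since the implied error comes from that p. Other transcripts per gene, another normalization, no expression filter, another pseudocount and leave-one-out were not run, since the tables hold genes and group means. No paired analysis was possible because values per library were not used here. Depth is unknown, and the self-test calls 61 to 77 percent of changes of 1 log2 unit.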

Other observations

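All tests in this part, and the genes named, were chosen only after the data had been seen.

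Beyond the fixed lists, 95 gene families were tested per comparison with cameraPR. The F-box protein genes fbxb had 72 lowered of 97 at 3 h of salt (median -1.99, adjusted p = 9.2e-11). At 24 h 62 of 103 were lowered (-1.05, adjusted p = 6.4e-06, or adjusted p = 0.075 with a correlation of 0.05). With skn-1 RNAi at 24 h 52 of 103 were raised (0.87, adjusted p = 1.4e-11). Early zygotic markers had -2.05, -1.12 and 0.05 in these comparisons. The sdz genes, found as zygotic targets of SKN-1, had 24 lowered of 29 at 3 h (-2.40, adjusted p = 2.9e-10) and 23 of 31 at 24 h (adjusted p = 5.9e-05). In dpy-7 the patched-related ptr genes had 22 raised of 23 (1.12, adjusted p = 6.4e-08), the cuticulin-like cutl genes 25 of 27 (1.61, adjusted p = 1.6e-06) and the transthyretin-related ttr genes 29 of 49 (0.60, adjusted p = 6.1e-06). Medians of epidermis (1.01), neuron (0.67) and muscle markers (0.60) were raised there too. Of 15 P-glycoprotein genes (pgp) 9 rose at 24 h of salt (1.02, adjusted p = 5.5e-11), beside intestine markers at 0.30. With skn-1 RNAi at that time 9 fell (-0.62, adjusted p = 5.4e-05), beside these markers at -0.44. Of 20 vacuolar ATPase genes (vha) 14 fell with skn-1 RNAi in dpy-7 (-0.23, adjusted p = 1.4e-06), beside intestine (-0.68) and muscle markers (-0.47). Neuropeptide genes (flp) were lowered by skn-1 RNAi at 24 h in 17 of 30 cases (-0.55, adjusted p = 8.3e-05), beside neuron markers at -0.65.

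Some genes went opposite ways in salt and mutant. The authors' deposited table gives ugt-44 at 0.68 for 24 h of salt and -1.19 for dpy-7, grl-16 at -0.81 and 1.07, and T26H5.9 at 2.15 and -4.70. Transcripts of the mitochondrial genome summed to 38302 TPM in the 24 h control and 19658 under salt. For dpy-7 they summed to 39196 TPM in the same control libraries and 18226 in the mutant. Of their 12 genes 0 were called at 24 h of salt and 1 was lowered in dpy-7, and the implied standard errors at 24 h of salt lay from 0.36 to 0.88, above the median of 0.19 over all genes. At 3 h they summed to 20232 and 24528 TPM, with 2 genes raised. Only the 24 h control exceeded 24528 TPM, and both falls rest on it.

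Genes of the pharynx were lower with skn-1 RNAi. A list of pharynx markers had 18 lowered of 25 at 24 h (median -1.09), 23 of 25 in dpy-7 (-2.09), and 5 lowered and 2 raised of 26 at 3 h (-0.16), where skn-1 itself was not lowered. The authors' deposited table gives the regulators ceh-34 at -1.95, -1.43 and -2.04, ceh-22 at -1.41, -1.23 and -2.30 and pha-4 at -1.11, -1.40 and -1.67 for 3 h, 24 h and dpy-7. Maternal SKN-1 specifies the embryonic blastomere that forms much of the pharynx, and gravid adults hold embryos. A hypothesis is that embryos without a pharynx inside the adults may lower these genes, which would spare body-wall muscle. Among markers not seen before, 10 of 16 were lowered at 24 h (-0.98) and 14 of 16 in dpy-7 (-2.02), against medians of -0.30 and -0.34 for body-wall muscle. Of the latter 6 of 10 were lowered in each and none raised, with 0.09% and 0.06% of random lists as low, so body-wall muscle was not spared there. At 3 h the medians were -0.13 and 0.13, a gap of 0.255, short of the 0.3 set for each comparison, so the hypothesis stays open. Knockdown in the adult pharynx was not tested.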
